A study of Homo sapiens with 4 samples.

How the data were processed

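Messenger RNA of NCI-H1703, an established human lung cancer cell line, was sequenced in 4 libraries. In 2 libraries the cells stably overexpressed the long noncoding RNA EGFR-AS1, and in the other 2 they carried the vector. Per the labels' protocols, both kinds of cells were grown in RPMI medium with serum under hygromycin, and strand-specific libraries with inserts of 250 to 300 bp were made by a sequencing provider. The submitters' processing notes name STAR (an aligner), HTSeq (a read counter), DESeq2 and the genome build hg19, with no versions and no roles. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. The authors deposited whole-number read counts per Ensembl gene, not normalized, with 1 column per library. Groups and the set letters A and B were taken from the sample titles. No deposited row lacked a gene identifier, and every column of counts was used.

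The table held 48162 genes, of which 22236 had no read in any library. A symbol from the reference tables was found for 33626 identifiers. The 14536 without one held 1.02% to 1.10% of the reads of a library, and these genes were tested and counted but not named. Chromosome, neighbour order, biotype, transcript length, GC content and overlaps between genes came from GENCODE release 29, which held 45342 of the identifiers and belongs to GRCh38. Because the authors' build was hg19, no coordinate is printed. As a hint on strand, 457 genes have at least 95% of their exonic bases under exons of the opposite strand. A count that ignored strand would be expected to leave such genes nearly empty where overlapping reads are discarded, but 249 of them had at least 10 reads and 112 had at least 100.

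Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest), with TMM factors, the filterByExpr filter at its minimum count of 10 and the group as the only term. All 4 libraries entered the fit. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. CPM, the depth-normalized counts, were computed from the deposited counts with the TMM factors, and are given as mean ± SD over 2 libraries. Fold changes are overexpression over vector. A fold against a group with no read was computed against 3 reads in each library of that group and is a lower bound. Where a group held 1 to 10 reads for a gene named for the size of its change, the ratio of the summed reads is given. It was scaled by the summed TMM-adjusted library totals of each group. Its exact 95% Clopper-Pearson interval was scaled alike and covers counting error only.

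The test, the gene lists, the rule for naming genes and most alternatives were set before the data were examined. The rule named EGFR-AS1, EGFR, PTBP1 and ELAVL1 whatever their values. It added the 10 largest rises and the 10 largest falls by fitted log2 fold change, among genes with a symbol, an adjusted p under 0.05, a mean of at least 1 CPM and groups that did not overlap. It also named the 3 genes with the smallest p, and up to 4 members with the smallest p of each list described. Not every gene that the rule names is described. Of 30 lists, the 28 with at least 3 tested members were tested with camera of limma 3.58.1, two-sided, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. The list members, UHRF1, CCL5, MMP12 and PECAM1, had no count under the identifier the reference gives, and are not analysed here. Counts of list members are over all genes tested, and counts adjusted over the list alone are given where they differ.

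The steps were tested on simulated data. In counts drawn for the 16106 tested genes at the observed means and depths, with 200 genes changed, the edgeR step recovered 26 of 67 genes changed 1.5-fold, 48 of 67 changed 2-fold and 60 of 66 changed 4-fold, with 6 false calls among 140. A list of 20 genes raised 1.5-fold had an adjusted p of 2.79e-40 by camera, and 0 of 29 unchanged lists were called. These simulated genes were independent of each other. A planted shift of -0.5 in 51 neighbouring genes gave a running median of -0.49, with 0 windows past the bound away from it.

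The alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library totals without factors, no filter on low counts, a filter of 1 CPM in 2 libraries, each library left out in turn, the set letter as a block, a log2 fold change of at least 1, and a test against a fold change of 1.2 (glmTreat). For the lists they were camera with an estimated correlation and fry. A fit without genes nearly off in 1 group and a fit without genes of shifted chromosomal segments were added after seeing the data. Running medians over neighbouring genes used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6. They covered 9811 coding genes with a mean of at least 5 CPM on chromosomes 1 to 22, in windows of 51 genes, after removal of lowess trends with GC content and length from log2(CPM + 0.5) differences. Figures were drawn with matplotlib 3.10.9.

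The libraries held 32601449 to 41518275 counted reads. The chi-square of the counts per degree of freedom was 24.0 between the vector libraries and 11.1 between the overexpression libraries, so no pair agreed within sampling noise. This cannot tell separate cultures from separate library preparations of the same RNA. Each library was counted as 1 replicate.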

Results

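RNA of NCI-H1703 lung cancer cells was profiled in 2 groups of 2 libraries, lettered A and B: cells made to overexpress the long noncoding RNA EGFR-AS1 and cells with the vector. The question was which transcripts differ when EGFR-AS1 is raised. The vector libraries held 41518275 and 32601449 counted reads and the overexpression libraries 32680467 and 33750041. Mitochondrially encoded genes took 2.21% to 2.83% of the reads of a library, and the 10 most abundant genes 4.63% to 5.29%. Across genes, log expression correlated at 0.991 between the vector libraries, 0.994 between the overexpression libraries and 0.972 to 0.974 between groups; genes are not independent replicates. The labels do not say that the libraries of a group came from separate cultures, so the p-values below measure only the spread between these libraries. All group values are means ± SD with n = 2.

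EGFR-AS1 was 14.5-fold higher in the overexpression libraries. Its level (ENSG00000224057) rose from 1.28 ± 0.154 CPM in vector to 18.8 ± 2.0 CPM, with 59 and 37 reads in vector A and B against 670 and 586 in overexpression A and B. The log2 fold change was 3.86 (SE 0.22, edgeR adjusted p = 5.62e-09). EGFR (ENSG00000146648), the receptor gene on chromosome 7 in which EGFR-AS1 lies on the opposite strand, was at 364 ± 42.3 CPM in vector and 416 ± 18.5 CPM with overexpression. Its log2 difference of 0.19 (SE 0.12, edgeR adjusted p = 0.352) did not pass the test. By the reference annotation EGFR-AS1 has 2 exonic stretches, of which 1 overlaps an EGFR exon and the other lies in an EGFR intron, and 6.63% of its exonic bases lie under EGFR exons. The libraries were strand-specific, but no source used here gives the strand setting of the counting, so EGFR-AS1 counts may include some EGFR reads. Per 1000 EGFR reads there were 4.16 and 2.98 EGFR-AS1 reads in vector and 50.3 and 40.6 with overexpression, a 12.7-fold ratio of the means.

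PTBP1 and ELAVL1, genes of RNA-binding proteins named in advance, were not past the threshold. PTBP1 was at 784 ± 69.4 CPM in vector and 615 ± 5.33 CPM with overexpression, a log2 difference of -0.35 (SE 0.12, edgeR adjusted p = 0.0612). Over 13 alternatives its adjusted p ranged from 0.00116 without vector A to 0.447 without overexpression B, and it passed in 6, DESeq2 among them (adjusted p = 0.0346). ELAVL1 was at 228 ± 15.7 and 200 ± 1.22 CPM (log2 difference -0.19, SE 0.12, edgeR adjusted p = 0.332).

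**Figure D1:**
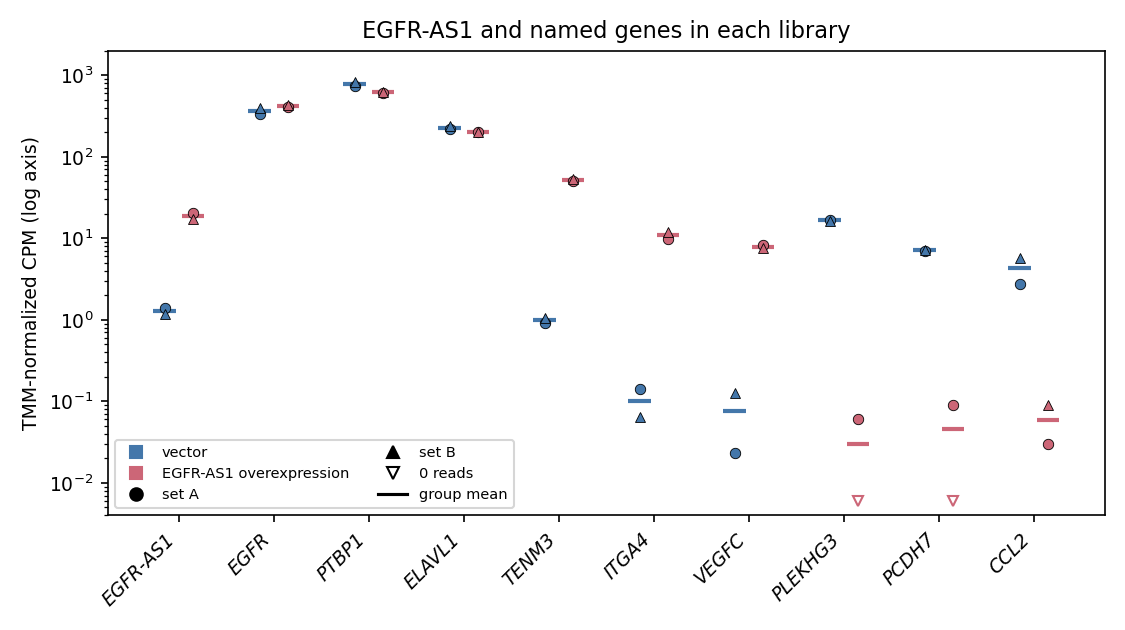
TMM-normalized CPM on a log axis for EGFR-AS1 and 9 other named genes in each library (circles, set A; triangles, set B; horizontal lines, group means; open triangles at the bottom, 0 reads). EGFR-AS1 stood at 1.28 CPM in vector and 18.8 CPM with overexpression, while the EGFR libraries of both groups lay close together.

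Several genes without a read in vector were well expressed with overexpression. FLRT3, a leucine-rich transmembrane protein of cell adhesion, had 0 reads in both vector libraries and 3476 and 3999 with overexpression (112 ± 9.73 CPM, at least 1348-fold higher, edgeR adjusted p = 2.00e-12). GJA1, which encodes the gap junction protein connexin 43, went from 0 reads to 53 ± 7.64 CPM (at least 638-fold, edgeR adjusted p = 2.27e-11). PCSK1N, an inhibitor of a prohormone convertase, reached 12.5 ± 2.65 CPM from 0 reads (at least 151-fold), and the ubiquitin ligase gene RNF128 reached 2.66 ± 0.307 CPM from 0 reads (at least 32.1-fold). TENM3, a teneurin that like FLRT3 binds latrophilin receptors, rose from 0.984 ± 0.0899 to 52.1 ± 2.02 CPM, a log2 fold change of 5.73 (SE 0.19, edgeR adjusted p = 2.27e-11). Its opposite-strand neighbour TENM3-AS1 had 2 reads in vector and 220 with overexpression (122-fold, 33.3 to 1011), with 2.40% of its exonic bases under exons of the opposite strand. As for EGFR-AS1, the strand setting is not given, so its reads may come from TENM3.

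The other genes of the 10 largest rises all had 1 to 8 reads in vector. They were the potassium channel subunit gene DPP6 (257-fold, interval 45.6 to 10182), the signalling adaptor gene DOK6 (116-fold, 56.3 to 291), the lymphatic growth factor gene VEGFC (117-fold, 49.8 to 362), the integrin gene ITGA4 (101-fold, 50.8 to 234) and the amino acid transporter gene SLC6A15 (94.8-fold, 32.1 to 463). VEGFC reached 7.92 ± 0.455 CPM, DOK6 11 ± 0.323 CPM and ITGA4 10.9 ± 1.35 CPM with overexpression. With so few vector reads the fitted changes moved with 1 library: that of VEGFC was 6.79, and 5.92 without vector A and 8.20 without vector B, and that of ITGA4 was 6.61, and 7.34 without vector A. All vector reads of DPP6 were in vector A and those of TENM3-AS1 in vector B, so without that library their vector count was 0.

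The largest falls were of the same order. PLEKHG3 fell from 16.6 ± 0.528 CPM to 2 reads in overexpression A and 0 in overexpression B (556-fold lower, interval 154 to 4595, edgeR adjusted p = 8.25e-10). The protocadherin gene PCDH7 fell from 526 reads to 3 (158-fold, 53.9 to 771), and the transcription factor gene PAX9 from 182 reads to 1 (164-fold, 29.2 to 6532). CCL2, a monocyte-attracting chemokine, fell from 4.27 ± 2.17 to 0.0596 ± 0.0416 CPM (67.6-fold, 26.1 to 250). ERN2, a sensor of unfolded proteins in the endoplasmic reticulum, fell 57.1-fold (30.9 to 120). CRACDL, LONRF2 and DMRTA2 had log2 fold changes of -3.56, -3.41 and -3.07. Without overexpression A the log2 changes of LONRF2 and DMRTA2 were -4.81 and -3.74; without overexpression B those of LONRF2, CCL2 and ERN2 were -2.71, -6.98 and -6.48. Without vector B that of CCL2 was -5.44. The last reads of PLEKHG3, PCDH7 and PAX9 were all in overexpression A. Their log2 changes without overexpression B were -8.02, -6.24 and -6.21, beside -8.95, -7.20 and -7.07 with all libraries. Without overexpression A no read was left in that group, so the fitted value is no measure of fold.

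Across all genes, 2332 of 16106 tested (14.5%) were called, 1257 higher and 1075 lower with overexpression (edgeR quasi-likelihood test). Of these, 901 changed by at least 1 on the log2 scale, 619 upward and 282 downward. Called genes included 2046 protein-coding genes, 179 long noncoding or antisense genes and 63 pseudogenes, whose reads can be shared with their parent genes, and 115 had no symbol. The groups did not overlap for 55.5% of tested genes, where chance gives 33.3%. Without overexpression A the count was 1299, without overexpression B 1271 and without vector A 3522.

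**Figure D2:**
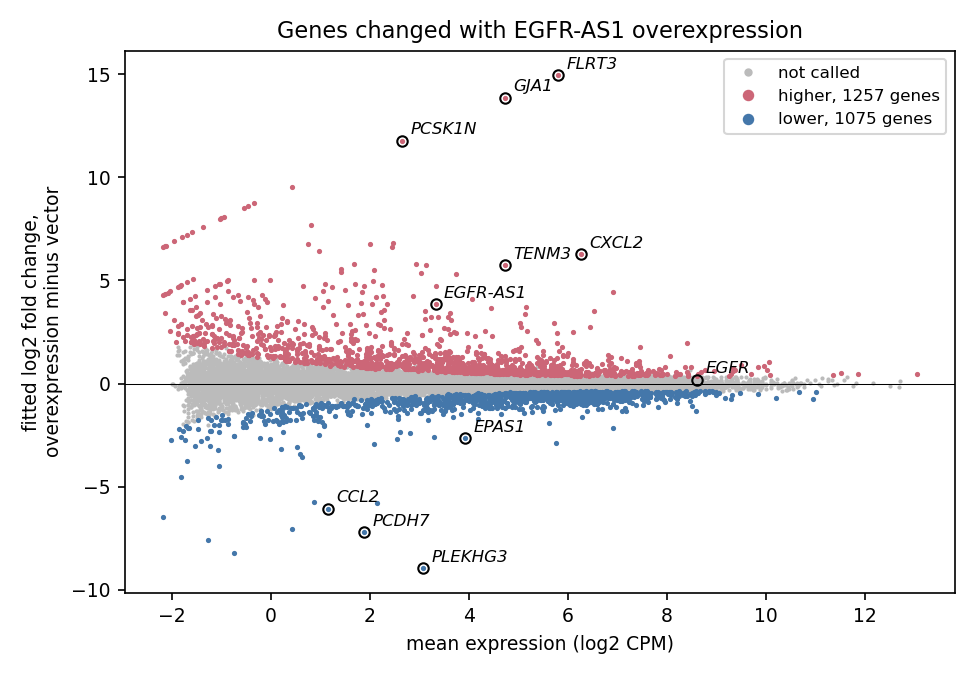
Fitted log2 fold change (overexpression minus vector) against mean expression (log2 CPM) of the 16106 tested genes; red, 1257 called higher; blue, 1075 called lower; grey, not called. Fitted values of genes without a read in 1 group, such as FLRT3, GJA1 and PCSK1N, depend on the fitting and are no measure of fold.

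Many of the genes that fell were neighbours on 3 chromosomes. On chromosome 14 the running median over 51 expressed coding genes reached -0.93 on the log2 scale between FANCM and DAAM1, where 51 of 51 genes were lower and 49 were called. On chromosome 2 it reached -0.68 between NCAPH and TMEM87B (51 of 51 lower, 42 called), and on chromosome 16 it was -0.61 between AXIN1 and GFER (48 of 51 lower, 38 called). On chromosome 8 it reached 0.40 between EXTL3 and HGSNAT (42 of 51 higher, 22 called). The segments were not these peak windows but the genes whose centred window passed 0.19, the bound from shuffled gene orders. They ran from PPP2R3C to DCAF4 on chromosome 14 and from ZNF514 to ORC4 on chromosome 2. On chromosome 16 the range was METRN to LCMT1, and on chromosome 8 it was WRN to MCM4. These 4 segments held 4.64% of the tested genes with a position. They also held 385 of the 1075 lower calls (35.8%), against 31 of the 1257 higher calls (2.47%). Because the segments were chosen by these same differences, and 3 of the 4 were downward, an excess of lower calls in them follows from the choice. The shares describe where the calls lie and are no test. PLEKHG3 and PAX9 lie in the chromosome 14 segment, CRACDL and LONRF2 in that of chromosome 2, and ERN2 in that of chromosome 16. Position was examined after the gene values were seen. Without the genes of all 11 segments past the bound, 1721 genes were called, 1077 higher and 644 lower.

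**Figure D3:**
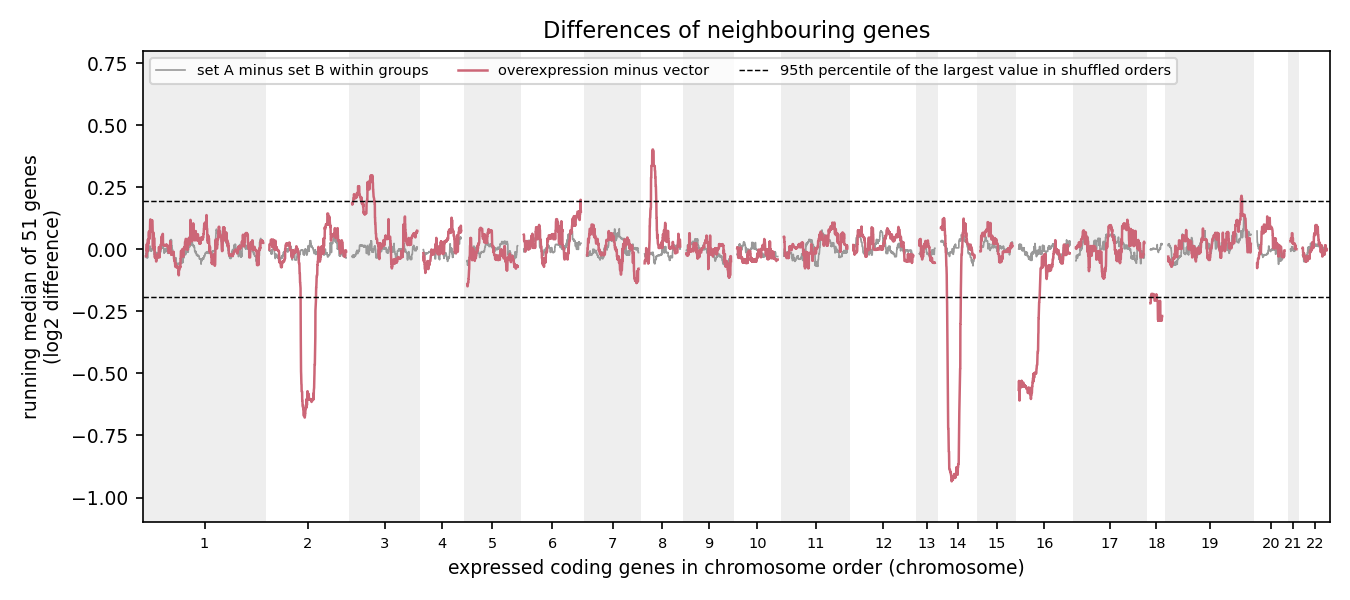
Running median over 51 neighbouring expressed coding genes of the log2 difference, in chromosome order, for overexpression minus vector (red) and for set A minus set B within groups (grey); dashed lines, 0.19 and its negative, the 95th percentile of the largest absolute value in 1000 shuffled gene orders. The red line steps down to -0.68, -0.93 and -0.61 on chromosomes 2, 14 and 16 and up to 0.40 on chromosome 8, and the grey line stays within 0.13 of 0.

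Of 22 tested genes of cholesterol synthesis and uptake, 10 were higher, 11 adjusted over the list alone, none was lower and 12 did not pass (camera adjusted p = 0.000125; adjusted p = 0.694 with an estimated correlation). ACAT2, which makes acetoacetyl-CoA, rose 3.00-fold from 28.4 ± 0.824 CPM (edgeR adjusted p = 3.16e-07), the sterol oxidase gene MSMO1 1.91-fold from 35.7 ± 0.282 CPM, and the sterol carrier gene STARD4 1.84-fold from 36.0 ± 0.899 CPM. Among interferon-stimulated genes, 8 of 29 were higher, 9 adjusted over the list alone, and none was lower (camera adjusted p = 0.000678; adjusted p = 0.694 with an estimated correlation). They were led by IFITM1, an antiviral membrane protein gene (18.8-fold to 13.9 ± 1.71 CPM, edgeR adjusted p = 2.22e-08), SAMD9 (9.37-fold to 21.5 ± 3.64 CPM), SAMD9L (7.24-fold to 8.14 ± 0.919 CPM) and IFI44 (9.10-fold to 1.26 ± 0.0575 CPM). Of the matrix metalloproteinases and plasminogen system, which cut extracellular matrix, 7 of 13 were higher, 8 adjusted over the list alone, and none was lower (camera adjusted p = 0.00175; adjusted p = 0.694 with an estimated correlation). PLAU, the urokinase gene, rose 3.72-fold to 8.49 ± 1.84 CPM and MMP2 3.28-fold to 2.97 ± 0.756 CPM; MMP16 rose 15.6-fold to 1.72 ± 0.0419 CPM, with log2 fold changes of 5.60 without vector A and 3.35 without vector B beside 3.97 with all libraries. None of the 7 lists past the threshold passed with an estimated correlation between genes. Fry, which tests a list for a shift in 1 direction, passed 0 lists (8 of 28 at an unadjusted p under 0.05, against 0 by camera with an estimated correlation). With 4 libraries, camera with an estimated correlation has few degrees of freedom. The estimates for NRF2 targets (-2e-04) and the EGFR family (-0.0327) were under the preset 0.01. Yet their unadjusted camera p rose from 0.0795 to 0.198 and from 0.154 to 0.273. Failing that alternative therefore does not show that correlation between genes made the lists pass. It does not exclude this either. For the 7 lists past the threshold the estimates were all above the preset 0.01. They ran from 0.0375 for interferon-stimulated genes to 0.512 for alveolar and airway genes, with 0.0816 for cholesterol synthesis.

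Of 24 genes of the unfolded protein and amino acid stress response, 7 fell, none rose and 17 did not pass (camera adjusted p = 0.000198; adjusted p = 0.694 with an estimated correlation). By fry in 1 direction the list had an unadjusted p of 0.116 (adjusted p = 0.223). The other lists past the camera threshold had unadjusted fry p of 0.00559 to 0.0398. By fry in either direction the stress response list did not pass either (adjusted p = 0.092). Its lowest camera value over the alternatives was in the fit without vector B, which leaves vector A alone in that group. DDIT4, an inhibitor of mTORC1, fell by 1.32 on the log2 scale (SE 0.16, from 205 ± 58.6 to 82.4 ± 4.24 CPM), the sestrin gene SESN2 from 128 ± 30.5 to 64.1 ± 2.34 CPM, the pseudokinase gene TRIB3 by 1.12 (SE 0.17) and the lipoprotein receptor gene VLDLR by 1.07 (SE 0.23). The log2 fold change of VLDLR was -0.63 without vector A. The vector libraries lay far apart for DDIT4 and TRIB3 (246 and 164 CPM, and 210 and 132 CPM), but all were above the overexpression libraries.

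Of 17 mesenchymal genes, 6 were higher, 7 adjusted over the list alone, and 1 was lower (camera adjusted p = 0.0119; adjusted p = 0.694 with an estimated correlation). CDH2, N-cadherin, rose 8.24-fold to 2.17 ± 0.0896 CPM, the fibronectin gene FN1 4.38-fold to 5.23 ± 0.762 CPM, ACTA2, smooth muscle actin, 3.63-fold to 8.39 ± 1.54 CPM, and the repressor gene ZEB2 1.88-fold to 28.7 ± 0.790 CPM. CDH2 and ZEB2 lie in shifted segments of chromosomes 18 and 2, where the running medians were lower. Without genes of shifted segments the list's camera adjusted p was 0.171. Its lowest value over the alternatives was in the fit without overexpression B, which leaves overexpression A alone in that group. The untested list member COL1A2 had 37 reads in overexpression A and at most 1 in each other library. Of 4 squamous and basal genes, SOX2, a lineage transcription factor, and SFN, stratifin, were higher (3 of 4 adjusted over the list alone) and none was lower (camera adjusted p = 0.00398; adjusted p = 0.694 with an estimated correlation). SOX2 rose 32.2-fold to 1.87 ± 0.295 CPM, with log2 fold changes of 4.24 without vector A and 6.12 without vector B beside 5.01. SFN rose 3.57-fold to 1.61 ± 0.506 CPM (edgeR adjusted p = 0.00428; over the alternatives 3.86e-05 to 0.135, the highest without overexpression A). The untested keratins of this list, KRT13 and KRT5, had 49 and 19 reads in overexpression A against 1 and 0 in overexpression B. Of 3 alveolar and airway genes, NKX2-1, the lung lineage transcription factor, rose 26.2-fold from 0.260 ± 0.0989 to 7.13 ± 0.253 CPM. NAPSA and AGER did not pass. The list had a camera adjusted p of 0.00200, with 0.694 at an estimated correlation and 0.0755 by limma-voom. Its lowest value over the alternatives was in the fit without overexpression B. Its untested member MUC5B had 22 reads in overexpression A and 1 to 3 in each other library. NKX2-1 lies in the chromosome 14 segment in which most genes, PAX9 among them, were lower.

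ERK pathway targets moved in both directions. Of 20 tested members, 5 were lower (6 adjusted over the list alone) and 2 higher, and the list did not pass (camera adjusted p = 0.254, in the lower direction; median 0.07, mean -0.11). The members with the smallest p were 4 feedback and transcription factor genes of that pathway, all lower: SPRY4 (log2 fold change -1.05, SE 0.13, edgeR adjusted p = 5.93e-05), DUSP6 (-1.75, SE 0.24), ETV5 (-0.83, SE 0.12) and ETV4 (-0.98, SE 0.18). The list's adjusted p ran from 0.00653 without overexpression A to 0.822 with an estimated correlation, and it was 0.462, in the higher direction, without overexpression B. Of the EGFR family and ligands, the ligand genes NRG1 (2.06-fold higher, to 92.0 ± 4.51 CPM) and EPGN (3.20-fold higher, to 2.93 ± 0.473 CPM) rose and the receptor gene ERBB2 fell by 0.41 (SE 0.12, edgeR adjusted p = 0.0247; 0.00311 to 0.286 over the alternatives, not past the threshold without either overexpression library). LRIG1, an inhibitor of these receptors, did not pass over all genes (edgeR adjusted p = 0.0742; 0.0264 to 0.655 over the alternatives, past the threshold at 0.0290 without vector A), and adjusted over the list alone it made 3 of 11 higher; camera gave an adjusted p of 0.254. NRG1 lies in the chromosome 8 segment whose genes were mostly higher.

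Of 20 receptor tyrosine kinases outside the EGFR family, 5 were higher and 5 lower, 6 adjusted over the list alone (camera adjusted p = 0.631, in the lower direction; median -0.25, mean 0.05). AXL rose 25.5-fold to 4.51 ± 0.414 CPM (log2 fold change 4.67, and 6.06 without vector A), FGFR1 2.07-fold from 697 ± 121 to 1442 ± 104 CPM and MET 1.94-fold to 230 ± 19.1 CPM. MERTK fell 2.29-fold from 62.3 ± 0.994 CPM. FGFR1 lies in the chromosome 8 segment and MERTK in that of chromosome 2.

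Inflammatory genes and NF-kB targets split into strong rises and strong falls, 5 up and 4 down of 20 (camera adjusted p = 0.144). The neutrophil chemokine genes CXCL2 (78.4-fold, to 153 ± 59.8 CPM, edgeR adjusted p = 3.45e-10) and CXCL8 (18.2-fold, to 8.22 ± 2.85 CPM) rose, while CCL2 fell as above and TNFAIP2 fell 3.31-fold from 27.6 ± 1.44 CPM. The list passed without vector B (adjusted p = 0.00274) and without overexpression B (adjusted p = 0.00112), and over all alternatives the adjusted p reached 0.803. Of 19 hypoxia targets, 1 was higher, 2 adjusted over the list alone, and 4 lower (camera adjusted p = 0.432, in the lower direction; median 0.02, mean -0.11). PLOD2, a collagen lysyl hydroxylase gene, rose 5.82-fold to 61.9 ± 3.24 CPM (edgeR adjusted p = 4.57e-09). EPAS1, which encodes HIF-2 alpha, fell 6.33-fold from 26.1 ± 3.52 CPM (edgeR adjusted p = 5.55e-08), and ADM, adrenomedullin, 3.79-fold from 77.3 ± 20.4 CPM. Of 22 p53 targets, 2 were higher and 2 lower (camera adjusted p = 0.631, in the lower direction; median 0.03, mean -0.07). GDF15, a stress-induced cytokine gene, fell 4.39-fold from 197 ± 84.1 to 44.8 ± 12.4 CPM and the death receptor gene FAS rose 1.75-fold to 23.1 ± 1.69 CPM.

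The remaining signalling lists did not pass with all libraries. Of 12 Wnt targets, 4 were higher and 1 lower, 2 adjusted over the list alone (camera adjusted p = 0.254, in the higher direction; median -0.09, mean 0.22). The secreted Wnt antagonist gene DKK1 rose 3.86-fold to 66.6 ± 3.05 CPM, DKK3, a gene of the same family, 2.79-fold to 35.6 ± 1.66 CPM, and LEF1, a nuclear effector of the pathway, 3.10-fold to 3.04 ± 0.608 CPM. That list's adjusted p was 0.0341 without overexpression B and up to 0.754 over the alternatives. Of 21 YAP/TAZ targets, 4 were higher, 7 adjusted over the list alone, and 1 lower (camera adjusted p = 0.113); GADD45A rose 2.59-fold to 163 ± 34.7 CPM and NUAK2 2.13-fold to 41.4 ± 9.77 CPM. It passed without vector B (adjusted p = 0.00208) and without overexpression B (adjusted p = 0.00744), and reached 0.754 with an estimated correlation. Of 15 Notch pathway genes, 2 were higher and 3 lower, 4 adjusted over the list alone (camera adjusted p = 0.632, in the lower direction; median -0.12, mean 0.04). The receptor gene NOTCH3 rose 2.03-fold to 36.3 ± 2.57 CPM and NRARP, a feedback inhibitor, fell 1.79-fold to 14.3 ± 1.76 CPM. Of 20 TGF-beta targets, 2 were higher, 3 adjusted over the list alone, and 4 lower (camera adjusted p = 0.638, in the lower direction; median -0.07, mean 0.06). CDKN2B, a cell cycle inhibitor gene, rose 3.10-fold to 13.7 ± 0.0263 CPM.

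In the lists of cell identity, KRT18 and KRT8, the simple epithelial keratins, fell 2.43-fold from 75.3 ± 10.3 CPM and 2.13-fold from 5.50 ± 0.570 CPM, and the claudin gene CLDN7 rose 3.35-fold to 1.65 ± 0.147 CPM. The log2 fold change of CLDN7 was 1.75, and 2.51 without vector A. KRT8 was not past the threshold without overexpression B (edgeR adjusted p = 0.128; from 1.71e-05 over the alternatives). These were the called members of 8 epithelial genes, 3 lower adjusted over the list alone (camera adjusted p = 0.117; 0.0359 without overexpression A and up to 0.747 over the alternatives). Of 13 stem-like cell markers, 3 were higher and 1 lower, 2 adjusted over the list alone (camera adjusted p = 0.497, in the higher direction; median -0.12, mean 0.38); beside SOX2, ALDH1A3 rose 2.01-fold to 49.8 ± 0.726 CPM. The list of 5 neuroendocrine markers did not pass (camera adjusted p = 0.254). Of the blood cell markers CD8A and ITGAM, and of the endothelial markers EGFL7 and ESAM, none passed, and these 2 lists had too few tested members for a list test.

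Of 24 DNA replication and G1/S genes, 1 was higher and 3 lower (camera adjusted p = 0.254), with MCM6, a helicase subunit gene, lower by 0.66 on the log2 scale (SE 0.12) within the chromosome 2 segment. Of 25 mitosis and G2/M genes, 1 was higher and 1 lower (camera adjusted p = 0.522), and PLK1, a mitotic kinase gene, fell by 0.62 (SE 0.12) within the chromosome 16 segment. Of 47 cytosolic ribosomal protein genes, RPS2 fell by 0.74 (SE 0.12) within that same segment and 46 did not pass (camera adjusted p = 0.458). Of 30 nuclear respiratory chain genes, 1 was higher and 2 lower (camera adjusted p = 0.885, in the lower direction; median 0.04); COX5B, lower by 0.73 (SE 0.12), lies in the chromosome 2 segment. Of 13 mitochondrially encoded genes, MT-ND6 was higher by 0.48 (SE 0.12, edgeR adjusted p = 0.0141; 0.000406 to 0.188 over the alternatives, not past the threshold without either overexpression library) and 12 did not pass (camera adjusted p = 0.519). Of 19 glycolysis enzymes, 3 were higher and none lower (camera adjusted p = 0.519); ENO2 rose 2.50-fold to 6.23 ± 0.880 CPM, with log2 fold changes of 2.0 without vector A, 0.89 without vector B and 1.32 with all libraries. Of 18 NRF2 targets, 5 were higher, 7 adjusted over the list alone, and 2 lower (camera adjusted p = 0.185), with AKR1C1, an aldo-keto reductase gene, 2.48-fold higher at 6.77 ± 1.10 CPM. The list of EGFR and its neighbours on chromosome 7 had 5 tested members, EGFR-AS1 and EGFR among them, and tested in the higher direction (camera adjusted p = 0.144; 0.0314 without vector B and up to 0.754 over the alternatives). Its 1 higher member was EGFR-AS1 itself. LANCL2 was lower by 0.55 (SE 0.14, edgeR adjusted p = 0.0119; 0.000110 to 0.0873 over the alternatives, not past the threshold without either overexpression library), and VOPP1 was also lower adjusted over the list alone.

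**Figure D4:**
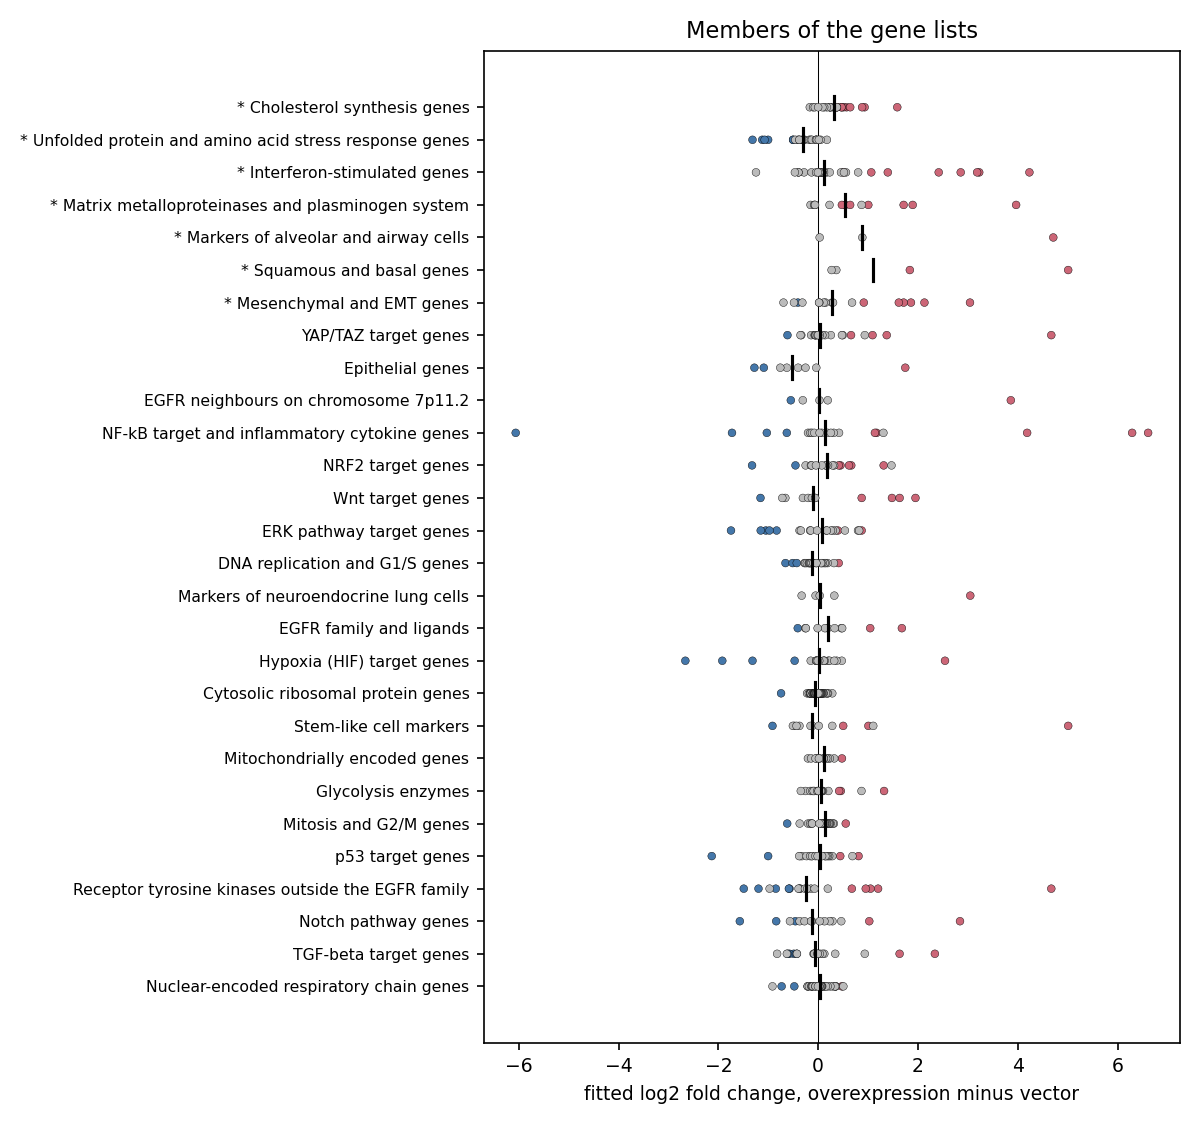
Fitted log2 fold change (overexpression minus vector) of each tested member of the 28 lists, ordered by camera adjusted p; red, called higher; blue, called lower; grey, not called; black bars, list medians; asterisks, the 7 lists past an adjusted p of 0.05 at the preset correlation. Cholesterol synthesis genes were called only on the higher side (10 of 22) and stress response genes only on the lower side (7 of 24).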

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

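The fits without genes nearly off in 1 group and without genes of shifted segments were chosen after seeing the data. In the 13 refits, no called gene that was tested again changed direction. EGFR-AS1 passed the threshold and EGFR did not in all 13, with log2 fold changes of 3.74 to 3.99 and 0.07 to 0.31. Between tools, scalings and filters the number of called genes was 2125 (DESeq2) to 2792 (no filter on low counts), against 2332. It was 901 with a log2 fold change of at least 1 and 1412 against a fold change of 1.2, both stricter by construction. Without 1 library it ran from 1271 (without overexpression B) to 3522 (without vector A), and it was 1299 without overexpression A. Of the 2332 genes, 1247 were called again without overexpression A and 1208 without overexpression B. In these fits the lone library of a group is assumed to vary like the other group. The share of called genes that were higher was 61.5% without overexpression B and 51.2% to 56.6% without each other library. Of the 1862 called genes outside shifted segments, 1721 were called without the genes of those segments, and 62.6% of these were higher. With the set letter as a block the count was 3467. The labels do not say whether a letter marks a shared culture or run. Deviations from the group means correlated at 0.169 across genes between libraries of the same letter, so a pairing by letter is not excluded. Depth and 2 libraries per group limit small changes: 38.8% of simulated 1.5-fold changes were recovered. The simulation changed 200 of 16106 genes, fewer than the 2332 called here. Recovery after adjustment depends on how many genes change, so that share need not hold for these data.

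The number of lists past the threshold was 7. It was 0 by camera with an estimated correlation (0 at an unadjusted p under 0.05), which has few degrees of freedom with 4 libraries. It was 0 by fry in 1 direction (8 unadjusted) and 25 by fry in either direction. Without 1 library it was 7 to 10, and without genes of shifted segments it was 5, where the alveolar and airway list had too few members to test, as with the filter of 1 CPM. Direction turned for 7 lists that were not past the threshold, and the cause was not tested. Leaving out 1 library gave adjusted p of 0.00653 to 0.644 for ERK targets, where the turned value was 0.462 without overexpression B, and 0.185 to 0.951 for mitosis. It gave 0.238 to 0.973 for Notch, 0.333 to 0.926 for TGF-beta, 0.0757 to 0.731 for ribosomal proteins, 0.193 to 0.848 for mitochondrially encoded genes and 0.403 to 0.874 for the respiratory chain. The respiratory chain list also turned by limma-voom (0.930), by fry in 1 direction (0.916) and without genes of shifted segments (0.794). Among named list members not past the threshold, direction turned without 1 library for KRT15 (log2 fold change -0.079 to 0.692), MT-ND1 (-0.485 to 0.0215), ESAM (-0.28 to 0.23), SYP (-0.25 to 0.18) and AGER (-0.32 to 0.51), and the cause was not tested.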

Other observations

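The tests of mixed cells, of segment loss behind nearly absent genes, of other splits, and of a tissue trace, its depth and its part in the group difference were chosen after the result was seen; the test of neighbouring genes had its bound set first, and was given a pattern of its own after its result.

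Some 15 genes had at most 3 reads over both libraries of 1 group and at least 1 CPM in the other, 11 of them expressed with overexpression (FLRT3 and GJA1 among them) and 4 in vector. Cells of another line mixed in beside vector-type cells would keep vector transcripts. Against that, 8 genes at 1 CPM or more in vector were at least 8-fold lower in both overexpression libraries, while the median of all genes was 0.004. Shifted segments did not cover the set as a whole, since 2 of the 15, PLEKHG3 and PAX9, lay in them. Both were among the 4 expressed in vector and nearly absent with overexpression. The running median of the chromosome 14 segment that holds them was -0.93 at its peak, which is 0.523-fold. By their counting intervals PLEKHG3 was at least 154-fold lower and PAX9 at least 29.2-fold lower. A loss that lowered these 2 genes only as much as their neighbours is therefore argued against. Segment loss as a part of their fall stays open. All 11 shifted segments held 6.38% of the tested genes with a position. Running medians over many neighbours cannot see loss or gain of a single gene, so focal change was not tested. An effect of EGFR-AS1, and cell populations that differed before or after the vectors were introduced, stay open and could not be separated with 1 line of each kind in the labels.

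Neighbouring genes shifted together in 11 segments, of which those on chromosomes 14, 2, 16 and 8 had the largest absolute running medians at their peaks. The largest absolute running median was 0.9349, above the highest of 1000 shuffled orders at 0.2508 (p = 0.001, the smallest they can give, one-sided permutation test). Bias from GC content or gene length is argued against: after removal of both trends the value exceeded the 95th percentile of shuffles by 0.7415. A difference between sets A and B is argued against as well, because the within-group value was 0.1388 of that between groups, though at 0.1298 it also passed its own shuffled bound of 0.0998. Regional copy-number differences between sublines or clones of the line are a candidate explanation whose needed values are present. Expression does not measure copy number, so an effect of EGFR-AS1 stays open, untested. The scan left out chromosome Y, of which RPS4Y1, DDX3Y, KDM5D and FAM224B were called lower. Genes of that chromosome were not tested as a set.

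Overexpression A held reads of genes that were nearly absent from the other libraries. In that library 38 genes had at least 10 reads and at most 1 in its replicate, and 11 had none in any other library. Vector A also stood apart from its replicate, with 55 such genes, but only 1 had no read in any other library. For vector B and overexpression B there were 2 and 4 such genes. Of 3 marker lists, used after the result was seen, 2 exceeded 10 times the mean of the other libraries. These were plasma cells with 252 reads (293-fold, with IGHG1 127, IGHG4 33, IGHG2 27) and stratified squamous epithelium with 150 (61.3-fold, with KRT13 49, KRT4 23, KRT5 19). The plasma cell marker IGKC had 0 reads in every library. KRT13 and KRT5 are also members of the squamous list above, so the marker lists describe the excess and are no independent test of it. Fits without overexpression B leave this library alone in its group. The mesenchymal, squamous, alveolar, matrix metalloproteinase, NF-kB and Wnt lists had their lowest adjusted p in that fit. YAP/TAZ targets also passed there. The part of these reads in those values was not tested. The fibroblast list was 1.79-fold higher, with DCN at 39 reads and 0 elsewhere. COL1A1 held most reads of that list in every library, with 348 of 518 in overexpression A. Deeper sequencing is argued against, since the library was not the deepest. Over the 3 lists it held 2.402 times the marker reads of the deepest, vector A, a value held down by COL1A1. For plasma cells it held 252 reads against 2 in vector A, and for squamous epithelium 150 against 3. The trace as the whole source of the group difference is argued against, since 1299 genes were called with that library left out, although single genes may owe part of their difference to it; a trace of RNA or reads from a tissue sample may be present, and its origin was not tested.

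Of the 3 splits of the 4 libraries into 2 and 2, 1 (the real one) called 2332 genes and the highest other called 0 by edgeR. At an unadjusted p under 0.05 there were 213 genes for set A against set B, and 22 for the other. In these other splits each side held 1 vector and 1 overexpression library. The group difference thus entered the spread within sides, so few calls were possible and their 0 decides nothing. Also, 3 splits are too few for a share under 0.05. Of 340 Fisher exact tests over 170 symbol families, two-sided, 0 showed more called genes than the rest at an adjusted p under 0.05 (15 unadjusted), and the RPL family held fewer higher calls than the rest (0 of 105, Fisher exact adjusted p = 0.0492).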
